A study of Mus musculus with 12 samples.

How the data were processed

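RNA of mouse cells and epiblast tissue was measured on 12 expression microarrays, 2 for each of 6 groups: ESC derived at E3.5, EpiSC derived at E5.75, rsEpiSC derived at E5.75 and at E6.5, and epiblast tissue of E5.75 and of E6.5. Total RNA was amplified and labelled with biotin, per the labels' protocols. The labels' protocol names an array for human genes, but the identifiers of the table match a mouse probe set table, which was used here. Other label fields call the rsEpiSC lines by another name, leave out the name of the factor in their medium, and give strain and passage fields that count up from array to array, so strain and passage were not used. Nothing in the labels says whether replicates are separate cultures, animals or litters.

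The deposited table holds log2 signal values of 41345 probe sets on 12 arrays (minimum 0.332, maximum 13.594, median 4.214, 0 missing), made with oligo and RMA per the submitters' processing notes. The versions of both and the settings of the normalization are not given in the sources used here. The values were taken as deposited, with no further normalization in the reported results. No arrays were identical: correlations between arrays over all genes ran from 0.872 to 0.988.

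Probe sets were named with the supplied probe set table: 23521 carried 1 gene symbol, 1814 several and 16010 none. Symbols were checked by gene identifier against a RefSeq table of the mouse genome GRCm38.p6, which held 99.18% of the identifiers of probe sets with 1 gene and changed 0 symbols. Only names, chromosomes and neighbouring genes were taken from that table. For the 1082 genes with more than 1 probe set, the probe set with the highest mean over all arrays was kept, leaving 22180 genes. Probe sets without a single gene entered only the alternative that tests every probe set. No filter on low signal was applied in the reported results.

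Differences were tested with limma 3.58.1 in R 4.3.3, with lmFit on 6 group means and eBayes with a trend of the variance on mean signal (residual degrees of freedom 6, prior degrees of freedom 5.99). The p-values were adjusted over all genes by the method of Benjamini and Hochberg, separately for each of 9 comparisons, and an adjusted p under 0.05 was taken as a difference, with the number of at least 2-fold given beside it. The comparisons were EpiSC against ESC, rsEpiSC E5.75 against EpiSC and against ESC, rsEpiSC E6.5 against rsEpiSC E5.75, epiblast E6.5 against epiblast E5.75, each rsEpiSC group against epiblast of its stage, EpiSC against epiblast E5.75, and the difference between stages in rsEpiSC minus that in epiblast as an interaction term. Changes of comparisons that share a group are not independent, and no overlap between such comparisons was computed.

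Gene lists were written from general knowledge, since no gene set collection was used: core pluripotency, naive pluripotency, post-implantation epiblast and primed state, primitive streak and mesoderm, anterior and neural ectoderm, definitive endoderm, visceral endoderm, extraembryonic ectoderm and trophoblast, fibroblast feeder markers, targets of Wnt/beta-catenin, Activin/Nodal, FGF/ERK and BMP signalling, primordial germ cells, germline genes silenced by DNA methylation, DNA methylation enzymes and regulators, glycolysis, oxidative phosphorylation, cholesterol biosynthesis, immediate early and stress response, cell cycle and proliferation, p53 targets, adhesion and epithelial to mesenchymal transition, and sex-linked genes. The 24 lists were tested in each comparison with camera of limma at a preset correlation of 0.01 and a trended variance, adjusted over the 24 lists, and again with a correlation estimated from the residuals and with the rotation test fry. Some genes are in several lists, so list tests are not independent.

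Genes were named by a rule that left out symbols of predicted genes and of small RNAs. In EpiSC against ESC and rsEpiSC E5.75 against EpiSC and against epiblast E5.75, they were among the 8 highest and 8 lowest. In the other comparisons they were among 5 and 5. All were genes that passed and whose groups did not overlap. Chance gives such a separation for 33.3% of genes with 2 arrays per group. Further named genes are, from each list described, up to 4 members that passed with the largest changes and up to 2 that did not pass, and in any comparison Pou5f1, Sox2, Nanog, Klf4, Esrrb, Zfp42, Fgf5, Otx2, Dnmt3b, Axin2 and Xist, with 1 further gene that is not analysed here. Genes named outside the rule are said to be named after their values were seen.

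Principal components were computed on all 22180 genes, centred and not scaled. Similarity to tissue is the Pearson correlation across genes of each cultured array with the mean of a tissue group, with the root mean square log2 difference beside it. Alternatives tried were the replicate number as a block, leaving out each array in turn (the lone array of its group is then assumed to vary like the other groups), only the arrays of the compared groups, a filter keeping the 15323 genes with at least 2 arrays above the median of all values, the mean of a gene's probe sets, every probe set without collapse, quantile normalization of the deposited values, arrays centred on their own median, eBayes without trend or robust, and array weights. For similarity the 1000 most variable genes were also used. Added later were a fit on the 8 cultured arrays, leaving out genes of the X and Y chromosomes, and a crossed pairing of replicates.

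The procedure was tested on simulated data with the means and variances of these genes and changes set in 200 genes between rsEpiSC E5.75 and EpiSC, 50 for each fold. It recovered 16% of genes changed 2-fold, 92% of those changed 4-fold and 100% of those changed 8-fold or 16-fold. It called 10 of 21980 unchanged genes. The simulated genes were independent and had the same variance in all 6 groups, whereas the real groups differ in spread. More genes passed between the real rsEpiSC E5.75 and EpiSC arrays (858) than were changed here. These shares therefore need not hold for the real data. A bound on a change was tested with treat of limma. Random gene lists matched on mean signal, where used, were drawn 10000 times.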

Results

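Gene expression was measured on 12 microarrays of mouse cells and tissue, in 6 groups of 2 arrays. Embryonic stem cells (ESC), derived at embryonic day (E) 3.5, were kept with CHIR99021 at 3 µM, which inhibits the kinase GSK3, PD0325901 at 1 µM, which inhibits the kinase MEK, and LIF. Epiblast stem cells (EpiSC), derived at E5.75, were kept with FGF2 at 12 ng/ml, Activin A at 20 ng/ml and serum replacement at 20%. The lines called rsEpiSC came from E5.75 and from E6.5, and were kept with IWR1 at 2.5 µM, which inhibits Wnt signalling, and a factor at 20 ng/ml that the labels do not name. All lines grew on feeder layers of mouse embryonic fibroblasts. The remaining groups were epiblast tissue of E5.75 and of E6.5, which is the pluripotent tissue of the embryo after implantation.

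The log2 signal of Klf4 was 9.47 in ESC and between 4.66 and 5.26 in the other 5 groups, and that of Fgf5 was 3.36 in ESC, 8.72 in epiblast E5.75 and 8.97 in epiblast E6.5 (means of 2 arrays). In a principal component analysis of 22180 genes, the first component (38.3% of the variance) set the 4 tissue arrays (scores 62.5 to 85.0) apart from the 8 cultured arrays (-54.6 to -21.3). The second component (21.5%) set the ESC arrays (68.6 and 78.1) apart from all others (-41.8 to 9.73). Replicate arrays correlated across genes at 0.943 in epiblast E5.75, 0.962 in epiblast E6.5, 0.965 in ESC, 0.976 in EpiSC, 0.986 in rsEpiSC E5.75 and 0.988 in rsEpiSC E6.5. The interquartile range of the genes was 2.23 to 2.68 on tissue arrays and 3.07 to 3.31 on cultured arrays.

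Differences below are log2 differences between group means ± the standard error of the fit, with 2 arrays per group. A gene rose or fell where the adjusted p of limma was under 0.05, and 24 gene lists were tested with camera at a preset correlation of 0.01. The comparisons, the gene lists, the tests and the first set of alternatives were chosen before the data were examined. The p-values measure only the spread between these samples, which may be technical, because nothing in the labels says that replicates are separate cultures or embryos. The Y-linked gene Eif2s3y had log2 signals of 2.72 and 8.19 on the ESC arrays and 5.16 and 2.33 on the rsEpiSC E5.75 arrays, so at least these pairs do not look like repeats of 1 sample. The number of arrays limits the precision. The fit takes 1 spread per gene from all 6 groups, but the groups differed in spread. The root mean square SD between replicates was 0.26 in rsEpiSC E5.75, 0.24 in rsEpiSC E6.5, 0.46 in epiblast E5.75 and 0.39 in epiblast E6.5. The numbers of genes that passed between the rsEpiSC stages and between the tissue stages therefore cannot be compared directly.

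**Figure D1:**
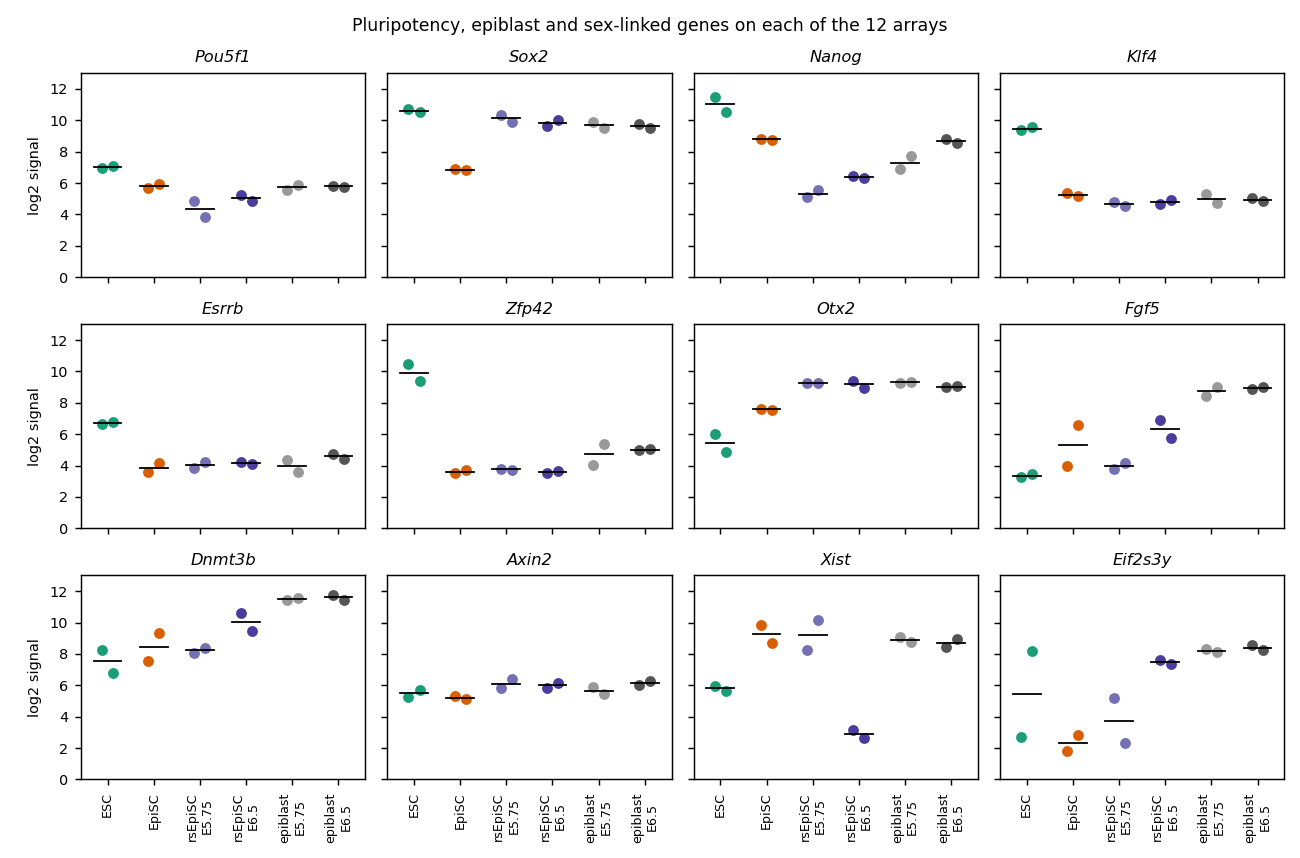
Log2 signal (y axis) of 12 genes in the 6 groups (x axis), where each point is 1 array and each line the mean of 2 arrays. Mean Nanog was 11.02 in ESC, 8.79 in EpiSC, 5.32 in rsEpiSC E5.75 and 8.67 in epiblast E6.5.

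EpiSC were compared with ESC to ask which genes separate lines from the epiblast after implantation from lines of the E3.5 embryo. Genes of naive pluripotency fell together in EpiSC: 17 of 20 measured members fell (18 adjusted over the list alone), with a median difference of -3.49. Among them were Nr0b1, which codes for an orphan nuclear receptor (-7.20 ± 0.46, adjusted p = 4.09e-06), Zfp42 (Rex1; -6.31 ± 0.42), Tbx3 (-5.69 ± 0.29), Klf4 (-4.21 ± 0.27) and Esrrb (-2.84 ± 0.31). In the list of the post-implantation epiblast and primed state 7 of 14 members rose (9 adjusted over the list alone; median 1.43), such as the homeobox gene Otx2 (2.17 ± 0.33), Zic5 (1.80 ± 0.45), Pim2 (1.79 ± 0.45) and Sfrp2 (1.65 ± 0.29). Fgf5 (1.92 ± 0.65, adjusted p = 0.125) and Cdh2 (1.81 ± 0.60, adjusted p = 0.119) did not pass. Of 9 core pluripotency genes, Sox2 (-3.74 ± 0.24), Dppa4 (-2.93 ± 0.35) and Nanog (-2.23 ± 0.35) fell, and Lin28a rose (1.14 ± 0.29). Pou5f1, which codes for Oct4, did not pass (-1.19 ± 0.33, adjusted p = 0.0547). Adjusted over the list alone, 2 core genes rose and 4 fell.

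Germline genes that DNA methylation silences in somatic cells were lower in EpiSC, where 7 of 15 fell (10 adjusted over the list alone; median -1.09), among them Hormad1 (-4.39 ± 0.73), Mael (-3.66 ± 0.40) and Dazl (-3.29 ± 0.34). Of 12 primordial germ cell genes 6 fell (8 adjusted over the list alone; median -1.01), such as Tcl1 (-4.83 ± 0.37), Dppa3 (Stella; -4.13 ± 0.37) and Kit (-2.65 ± 0.43). Of 9 DNA methylation enzymes and regulators 3 fell (adjusted over the list alone, 1 rose and 3 fell): Dnmt3l (-4.51 ± 0.47), Tet2 (-3.20 ± 0.37) and Tet1 (-1.33 ± 0.30). Dnmt3b did not pass (0.91 ± 0.55, adjusted p = 0.498). Targets of FGF/ERK signalling, which the ESC medium inhibits at MEK, rose in 7 of 15 cases and fell in 1 (8 and 2 adjusted over the list alone), including Egr1 (2.76 ± 0.46), Spred1 (2.38 ± 0.33) and Etv4 (1.81 ± 0.34). The one that fell was Spry2 (-2.08 ± 0.49). In the adhesion and epithelial to mesenchymal transition list 6 of 19 rose and 3 fell (9 and 5 adjusted over the list alone), such as the intermediate filament gene Vim (3.28 ± 0.50), Esrp1 (2.57 ± 0.64) and Cldn7 (-2.58 ± 0.53). In the cholesterol biosynthesis list 3 of 17 rose, Dhcr7 (1.60 ± 0.28), Fdps (1.50 ± 0.28) and Mvd (1.43 ± 0.33), and the same 3 did so adjusted over the list alone.

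Fibroblast marker genes moved with this comparison as well: 4 of 17 rose in EpiSC (8 adjusted over the list alone; median 0.66), namely Tagln (4.37 ± 0.34), Col1a2 (4.30 ± 0.63), Acta2 (3.13 ± 0.33) and Mmp2 (1.53 ± 0.41). The non-coding RNA Xist, which is transcribed from the inactive X chromosome, rose by 3.48 ± 0.54. Its log2 signals were 5.96 and 5.64 on the ESC arrays and 9.84 and 8.72 on the EpiSC arrays. Those of Eif2s3y were 2.72 and 8.19 against 1.81 and 2.86 (-3.12 ± 1.30, adjusted p = 0.236). The labels do not give the sex of the lines, and its part in these values was not tested. Among the highest of all genes were Sema3e (5.29 ± 0.36), Fndc3c1 (4.59 ± 0.31), Slc39a8 (4.41 ± 0.35) and Enpp3 (4.31 ± 0.42). Among the lowest were Arl14epl (-6.45 ± 0.30), Zfp992 (-6.35 ± 0.56), Jam2 (-6.04 ± 0.37), Slc38a4 (-5.97 ± 0.72) and Rps4l (-5.78 ± 0.46). In limma 1396 of 22180 genes passed, of which 798 rose and 598 fell, 1341 by at least 2-fold. Camera passed 10 lists, with an adjusted p of 1.58e-39 for naive pluripotency, 5.3e-12 for germline genes, 7.8e-09 for primordial germ cell genes and 1.47e-05 for fibroblast markers. It also passed the primed state (1.31e-08, but adjusted p = 0.0696 with an estimated correlation), core pluripotency (0.0104, but adjusted p = 0.244 with an estimated correlation) and FGF/ERK targets (0.000453, but adjusted p = 0.323 with an estimated correlation). The others were cholesterol biosynthesis (0.000448, but adjusted p = 0.231 with an estimated correlation), adhesion (0.0207, but adjusted p = 0.281 with an estimated correlation) and DNA methylation (0.047, but adjusted p = 0.502 with an estimated correlation). Without EpiSC replicate 1 the count of genes was 829 and without EpiSC replicate 2 it was 918. A fit on only the 4 arrays compared gave 558, 281 higher and 277 lower. Without ESC replicate 2 more genes fell (604) than rose (514). Of 46 named genes that passed, 38 still did without EpiSC replicate 1, 40 without EpiSC replicate 2, 41 without ESC replicate 1 and 40 without ESC replicate 2. Tested over every probe set 37 of the 46 still passed, 41 in the fit on the 8 cultured arrays and 42 with array weights. In the fit on the 4 arrays compared 30 still passed, and Otx2, Zic5, Pim2, Sfrp2, Egr1, Vim and Tet1 were among those that did not.

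**Figure D2:**
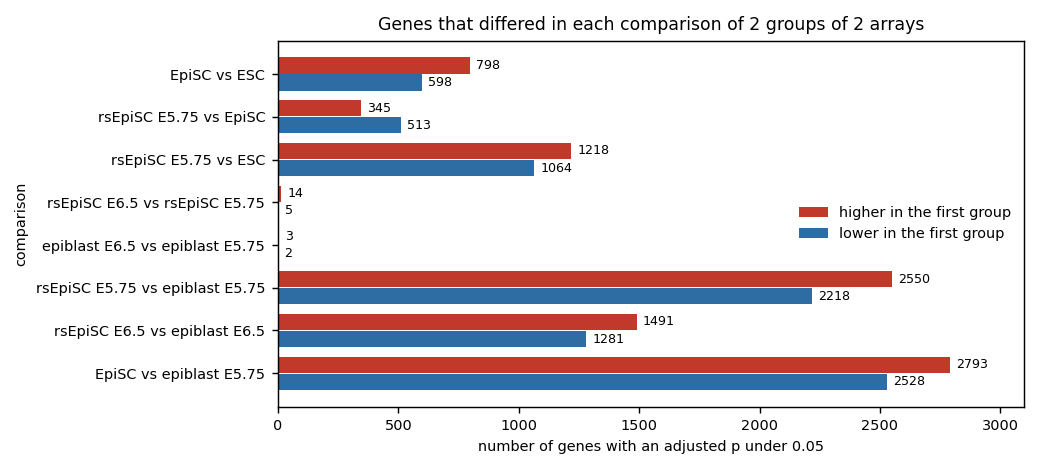
Number of genes with an adjusted p under 0.05 in limma (x axis) in 8 comparisons (y axis), where bars give the genes that were higher or lower in the first group. The counts ranged from 3 higher and 2 lower between the tissue stages to 2793 higher and 2528 lower in EpiSC against epiblast E5.75.

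The comparison of rsEpiSC E5.75 with EpiSC asks how lines derived at the same stage but kept in different media differ. Anterior and neural ectoderm genes rose in rsEpiSC, 6 of 14 measured members (8 adjusted over the list alone), with a median difference of 1.28. They included Hesx1, a homeobox gene of the anterior neural plate (3.62 ± 0.61), Lhx5 (3.35 ± 0.40), Sox1, an early neural gene (2.57 ± 0.31), and Rax, a gene of the eye field (2.52 ± 0.33). Tubb3 (2.84 ± 0.82, adjusted p = 0.089) and Six3 (1.02 ± 0.29, adjusted p = 0.0891) did not pass. Activin/Nodal targets fell in 7 of 13 cases (7 adjusted over the list alone; median -1.38), with Tdgf1, which codes for the Nodal co-receptor Cripto, at -7.27 ± 0.61 (adjusted p = 9.05e-05), Lefty1 at -2.84 ± 0.65, Foxh1 at -2.60 ± 0.45 and Skil at -2.50 ± 0.30. Nodal did not pass (-1.38 ± 0.56, adjusted p = 0.283). The adhesion list had 10 of 19 members that fell and 2 that rose (10 and 3 adjusted over the list alone), including the tight junction gene Cldn6 (-6.15 ± 0.68), the E-cadherin gene Cdh1 (-6.10 ± 0.82), Epcam (-4.45 ± 0.53) and Cldn4 (-4.30 ± 0.39). The N-cadherin gene Cdh2 rose (3.31 ± 0.60).

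Of 9 core pluripotency genes 4 fell and 2 rose in rsEpiSC (5 and 2 adjusted over the list alone): Utf1 (-4.39 ± 0.37), Nanog (-3.47 ± 0.35) and Pou5f1 (-1.47 ± 0.33) fell together with Tdgf1. Sox2 rose (3.26 ± 0.24, adjusted p = 4.32e-05). Naive pluripotency genes fell in 4 of 20 cases and rose in 1 (6 and 2 adjusted over the list alone), such as Nr5a2 (-3.81 ± 0.41), Klf5 (-2.56 ± 0.31) and Fbxo15 (-2.04 ± 0.30). The naive genes Klf4 (-0.60 ± 0.27, adjusted p = 0.357), Esrrb (0.16 ± 0.31, adjusted p = 0.954) and Zfp42 (0.13 ± 0.42, adjusted p = 0.979) did not pass. Primed state genes rose in 4 of 14 cases (adjusted over the list alone, 4 rose and 1 fell): Cdh2, Lef1 (2.43 ± 0.27), Sall2 (2.03 ± 0.29) and Otx2 (1.70 ± 0.33). Fgf5 was at -1.30 ± 0.65 (adjusted p = 0.432) and Dnmt3b at -0.21 ± 0.55 (adjusted p = 0.969). The cholesterol biosynthesis list had 8 of 17 members that rose (11 adjusted over the list alone; median 1.16), such as Hmgcs1 (2.03 ± 0.24), Lss (1.96 ± 0.35), Cyp51 (1.47 ± 0.30) and Mvd (1.42 ± 0.33).

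Targets of p53 fell in 4 of 13 cases (6 adjusted over the list alone; median -0.71), namely Perp (-2.80 ± 0.70), Fas (-2.31 ± 0.31), Mdm2 (-1.84 ± 0.31) and Phlda3 (-1.49 ± 0.35). Of 18 cell cycle genes 2 rose (3 adjusted over the list alone; median 0.47), the DNA replication genes Mcm6 (1.23 ± 0.26) and Mcm3 (0.94 ± 0.23). Fibroblast markers fell in 2 of 17 cases (5 adjusted over the list alone; median -0.24), Tagln (-1.85 ± 0.34) and S100a4 (-1.65 ± 0.40). Of 27 oxidative phosphorylation genes 22 had lower values (median -0.19) and no single gene passed in limma, with 1 at an unadjusted p under 0.05. Among the highest genes were Fezf2, a transcription factor gene of the forebrain (4.59 ± 0.35), Frzb, which codes for a secreted Wnt antagonist (4.39 ± 0.48), Ptn (4.31 ± 0.38) and Mid1 (4.26 ± 0.26). The imprinted long RNA Rian (3.85 ± 0.38), Wnt1 (3.68 ± 0.47) and Tox3 (3.59 ± 0.32) rose as well. Among the lowest were Platr10 (-5.36 ± 0.39), Apela (-5.08 ± 0.66), Atp1b1 (-4.72 ± 0.37), Hspb1 (-4.55 ± 0.23) and S100a10 (-4.54 ± 0.50).

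The 13 other lists did not pass in this comparison. Of 16 Wnt/beta-catenin targets only Lef1 rose (adjusted over the list alone, 3 rose and 1 fell; camera adjusted p = 0.152), with Axin2 at 0.90 ± 0.30 (adjusted p = 0.164). BMP targets rose in 3 of 10 cases and fell in 1 (3 and 1 adjusted over the list alone; 0.34): Id3 (3.31 ± 0.78), Id1 (2.11 ± 0.42), Id2 (1.76 ± 0.41) and Smad7 (-1.80 ± 0.33). FGF/ERK targets had 1 of 15 that rose, Dusp4 (1.60 ± 0.36), and 1 that fell, Ier3 (-1.96 ± 0.38; 3 and 3 adjusted over the list alone; 0.146). In the primitive streak and mesoderm list Eomes fell (-1.07 ± 0.26), 1 of 24 (adjusted over the list alone, 1 rose and 3 fell; 0.872), and its median (0.06) differed in sign from its mean (-0.04) and its test. Definitive endoderm genes gave 1 of 12 that rose, Cxcr4 (2.41 ± 0.41), and 2 that fell, Trh (-3.41 ± 0.79) and Krt19 (-3.11 ± 0.37; 1 and 2 adjusted over the list alone; 0.616). In the trophoblast list 1 of 17 rose, Fgfr2 (1.33 ± 0.32), and Eomes fell (2 and 1 adjusted over the list alone; 0.616). Primordial germ cell genes rose in 2 of 12 cases, Sox2 and Kit (2.02 ± 0.43; 2 adjusted over the list alone; 0.244). DNA methylation genes rose in 2 of 9, Uhrf1 (1.22 ± 0.28) and Dnmt1 (0.88 ± 0.19; 3 adjusted over the list alone; 0.242). Aldoc rose (1.58 ± 0.34) and Ldhb fell (-2.06 ± 0.42) among 17 glycolysis genes (2 and 1 adjusted over the list alone; 0.125). Trib3 (-2.44 ± 0.45) and Ddit3 (-2.32 ± 0.58) fell among 18 immediate early and stress genes (5 adjusted over the list alone; 0.1). No member passed in limma among 18 visceral endoderm genes (2 at an unadjusted p under 0.05; camera 0.616), 15 germline genes (0 at an unadjusted p under 0.05; 0.673) or 4 sex-linked genes (1 at an unadjusted p under 0.05; 0.313), where Xist was at -0.07 ± 0.54 (adjusted p = 0.991).

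In limma 858 of 22180 genes passed between rsEpiSC E5.75 and EpiSC, 345 higher and 513 lower, 831 by at least 2-fold. Camera passed 11 lists, with an adjusted p of 4.93e-08 for anterior and neural ectoderm, 9.12e-09 both for Activin/Nodal targets and for adhesion, 2.19e-12 for cholesterol biosynthesis and 0.000994 for naive pluripotency. Core pluripotency (0.00327, but adjusted p = 0.172 with an estimated correlation), the primed state (0.00818, but adjusted p = 0.316 with an estimated correlation) and p53 targets (5.42e-06, but adjusted p = 0.213 with an estimated correlation) passed at the preset correlation. So did the cell cycle (8.48e-06, but adjusted p = 0.213 with an estimated correlation), fibroblast markers (0.0116, but adjusted p = 0.0956 with an estimated correlation) and oxidative phosphorylation (0.00818, but adjusted p = 0.437 with an estimated correlation). The count of genes was 322 without rsEpiSC E5.75 replicate 1, 318 without rsEpiSC E5.75 replicate 2, 402 without EpiSC replicate 1, and 1567 with array weights. Of 65 named genes that passed, 36 still did without rsEpiSC E5.75 replicate 1, 37 without rsEpiSC E5.75 replicate 2, 41 without EpiSC replicate 1 and 46 without EpiSC replicate 2. In the fit on the 4 arrays compared 59 of the 65 passed, without Pou5f1. Tested over every probe set 42 passed, and Pou5f1, Lefty1, Id1, Id2, Id3, Eomes, Mcm3 and Perp were among the 23 lost. It was 60 after quantile normalization, 60 with centred arrays and 61 in the fit on the 8 cultured arrays. Hesx1 passed in 3 of the 4 fits with an array left out, Pou5f1, Lefty1 and Cdh2 in 1, and Otx2 in none.

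**Figure D3:**
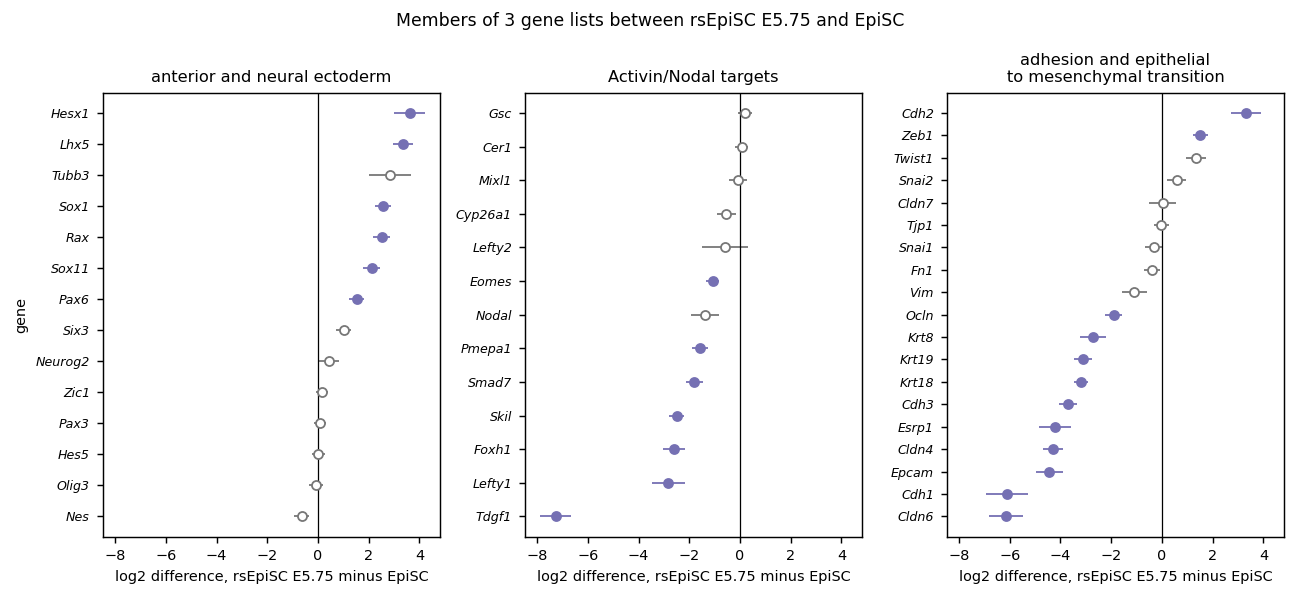
Log2 difference ± standard error between rsEpiSC E5.75 and EpiSC (x axis) of each measured member (y axis) of 3 gene lists, where filled points have an adjusted p under 0.05. Values run from -7.27 for Tdgf1 to 3.62 for Hesx1.

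The comparison of rsEpiSC E5.75 with ESC asks which genes separate rsEpiSC from the naive state. Naive pluripotency genes fell in 19 of 20 cases (19 adjusted over the list alone, where 1 rose; median -4.36), such as Nr0b1 (-7.08 ± 0.46), Zfp42 (-6.18 ± 0.42), Tbx3 (-5.80 ± 0.29), Tfcp2l1 (-5.49 ± 0.29), Klf4 (-4.81 ± 0.27) and Esrrb (-2.68 ± 0.31). Core pluripotency genes fell in 6 of 9 cases and rose in 1 (6 and 1 adjusted over the list alone; median -3.12), with Tdgf1 at -7.60 ± 0.61, Nanog at -5.70 ± 0.35 and Pou5f1 at -2.67 ± 0.33. Sox2 did not pass (-0.48 ± 0.24, adjusted p = 0.293). Primed state genes rose in 9 of 14 cases (11 adjusted over the list alone; median 1.54): Cdh2 (5.12 ± 0.60), Otx2 (3.87 ± 0.33), Lef1 (2.44 ± 0.27) and Sall2 (2.43 ± 0.29) rose. Fgf5 (0.62 ± 0.65, adjusted p = 0.738) did not pass. Anterior and neural genes rose in 8 of 14 cases (9 adjusted over the list alone; median 1.32), such as Lhx5 (3.12 ± 0.40), Hesx1 (3.00 ± 0.61) and Rax (2.60 ± 0.33). Cholesterol biosynthesis genes rose in 12 of 17 cases (adjusted over the list alone, 15 rose and 1 fell; median 1.73), such as Dhcr7 (2.99 ± 0.28), Mvd (2.85 ± 0.33) and Fdps (2.66 ± 0.28). Of 15 FGF/ERK targets 6 rose and 1 fell (7 and 1 adjusted over the list alone), with Egr1 at 3.49 ± 0.46, Dusp4 at 3.00 ± 0.36 and Spred1 at 2.97 ± 0.33. Among the highest genes were Prtg (6.11 ± 0.24), the retinoic acid binding protein gene Crabp2 (6.05 ± 0.25), Ptn (5.77 ± 0.38) and Ccnd2 (5.37 ± 0.53). Fibroblast markers rose in 4 of 17 cases (4 adjusted over the list alone), including Col1a2 (4.44 ± 0.63), Mmp2 (2.59 ± 0.41) and Tagln (2.52 ± 0.34).

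Between rsEpiSC E5.75 and ESC 2282 of 22180 genes passed in limma, 1218 higher and 1064 lower, 2078 by at least 2-fold. Camera passed 13 lists, among them naive (2.21e-37) and core pluripotency (9.32e-07), the primed state (3.98e-11), anterior and neural ectoderm (3.13e-07) and cholesterol biosynthesis (1.66e-13). It passed germline genes (8.58e-11; 9 of 15 fell, 11 adjusted over the list alone) and primordial germ cell genes (1.32e-05; 4 of 12 fell, 4 adjusted over the list alone). Activin/Nodal targets (3.12e-05, but adjusted p = 0.0552 with an estimated correlation), adhesion (0.000233, but adjusted p = 0.0731 with an estimated correlation) and fibroblast markers (0.0375, but adjusted p = 0.112 with an estimated correlation) passed at the preset correlation. It also passed FGF/ERK targets (6.55e-05, but adjusted p = 0.207 with an estimated correlation), the cell cycle (4.56e-05, but adjusted p = 0.21 with an estimated correlation) and p53 targets (0.00042, but adjusted p = 0.275 with an estimated correlation). This count was 1027 without rsEpiSC E5.75 replicate 1 and 1092 without rsEpiSC E5.75 replicate 2. Without ESC replicate 2 more genes fell (941) than rose (745). Of 29 named genes that passed, Hesx1 did not pass without rsEpiSC E5.75 replicate 1 or without ESC replicate 2, and the other 28 passed whichever array was left out.

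The comparison of rsEpiSC E6.5 with rsEpiSC E5.75 asks whether the stage of derivation leaves a difference between lines in the same medium. Of 19 genes that passed, 14 rose and 5 fell, all by at least 2-fold. The highest were the imprinted gene Nnat (4.69 ± 0.66, adjusted p = 0.0209), Utf1, a chromatin gene of pluripotent cells (3.32 ± 0.37), Car4 (3.14 ± 0.37), Tubb2a (2.94 ± 0.35) and Lyplal1 (2.94 ± 0.31). Those that fell were Xist (-6.30 ± 0.54, adjusted p = 0.000719), Mid1 (-3.81 ± 0.26, adjusted p = 0.000114), Thbs1 (-2.59 ± 0.37), Pmel (-2.50 ± 0.35) and Dmrt3 (-2.46 ± 0.35). Of the 19 genes 4 lie on the X or Y chromosome. Xist had log2 signals of 8.23 and 10.19 on the rsEpiSC E5.75 arrays and 3.17 and 2.65 on the rsEpiSC E6.5 arrays, and the Y-linked gene Eif2s3y had 5.16 and 2.33 against 7.64 and 7.36 (3.75 ± 1.30, adjusted p = 0.731). In limma 1033 genes had an unadjusted p under 0.05. If no gene differed, a share of 0.05 of the 22180 genes would be set to have such a p, which is more than 1033. The same share is the reference for the other counts at an unadjusted p under 0.05.

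Cholesterol biosynthesis genes had lower values in rsEpiSC E6.5 for 16 of 17 members (median -0.66), such as Mvd (-1.01 ± 0.33, adjusted p = 0.66), and none passed in limma, with 7 at an unadjusted p under 0.05. Primed state genes had higher values for 10 of 14 members (median 0.63), none passing in limma (6 at an unadjusted p under 0.05, 5 adjusted over the list alone), such as Fgf5 (2.34 ± 0.65, adjusted p = 0.468) and Pim2 (1.88 ± 0.45, adjusted p = 0.267). Of 9 core pluripotency genes Utf1 rose (3 adjusted over the list alone; median 0.45). Fibroblast markers had lower values for 14 of 17 members (median -0.18), none passing in limma (4 at an unadjusted p under 0.05, 3 adjusted over the list alone), with Col1a2 at -2.84 ± 0.63 (adjusted p = 0.216) and Tagln at -1.90 ± 0.34 (adjusted p = 0.101). No gene passed in limma in the adhesion list (9 at an unadjusted p under 0.05; median 0.25), where Cdh1 was at 3.23 ± 0.82 (adjusted p = 0.36), or among FGF/ERK targets (4 at an unadjusted p under 0.05; median -0.14). Camera passed these 6 lists at the preset correlation and none with an estimated one: cholesterol biosynthesis (2.45e-08), the primed state (4.02e-06), core pluripotency (0.000378) and fibroblast markers (0.0151), each with adjusted p = 0.164 with an estimated correlation. The others were adhesion (0.0496, but adjusted p = 0.381 with an estimated correlation) and FGF/ERK targets (0.0496, but adjusted p = 0.518 with an estimated correlation). The count of genes was 3 without rsEpiSC E6.5 replicate 1 (1 higher and 2 lower), 7 without rsEpiSC E5.75 replicate 1 (4 and 3) and 8 without rsEpiSC E5.75 replicate 2 (3 and 5). It was 157 in a fit on the 4 arrays compared (69 and 88), 257 with array weights (130 and 127) and 10 in a fit on the 8 cultured arrays (7 and 3). Of 10 named genes that passed, 2 still did without rsEpiSC E6.5 replicate 1, 6 without rsEpiSC E6.5 replicate 2 and 4 without either rsEpiSC E5.75 array. Xist and Mid1 passed whichever array was left out, but Mid1 did not pass with the mean of a gene's probe sets. Tested over every probe set, and in the fit on the 8 cultured arrays, 6 of the 10 passed, without Nnat, Thbs1, Pmel and Dmrt3. With each array centred on its own median 12 genes rose and 7 fell.

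Epiblast tissue of E6.5 was compared with that of E5.75 to ask what changes in the embryo between these stages. Mixl1, a homeobox gene of the primitive streak, rose (3.49 ± 0.37, adjusted p = 0.0128), as did Daam1 (2.13 ± 0.28, adjusted p = 0.0468) and the microRNA gene Mir3070a (2.07 ± 0.29), which was named after its value was seen. The pluripotency-associated gene Dppa2 (-2.90 ± 0.40) and the histone gene H4c9 (-2.54 ± 0.34) fell. Mixl1 was 1 of 24 primitive streak and mesoderm genes to rise (4 adjusted over the list alone; median 0.20; camera adjusted p = 0.316). Eomes (1.68 ± 0.26, adjusted p = 0.0748) and Rspo3 (1.37 ± 0.29, adjusted p = 0.147) did not pass. Germline genes had lower values at E6.5 for 12 of 15 members (median -0.54), none passing in limma (5 at an unadjusted p under 0.05, 4 adjusted over the list alone), such as Hormad1 (-2.99 ± 0.73, adjusted p = 0.169) and Sycp1 (-2.51 ± 0.36, adjusted p = 0.0548). Cholesterol biosynthesis genes had lower values for 15 of 17 members (median -0.44), none passing in limma (3 at an unadjusted p under 0.05, 1 adjusted over the list alone), such as Msmo1 (-1.42 ± 0.35, adjusted p = 0.169). Nanog was at 1.38 ± 0.35 (adjusted p = 0.176).

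Limma passed 5 of 22180 genes between the tissue stages, 3 higher and 2 lower, all by at least 2-fold, with 2819 at an unadjusted p under 0.05. Camera passed germline genes (0.00136, but adjusted p = 0.379 with an estimated correlation), Activin/Nodal targets (0.00251, but adjusted p = 0.379 with an estimated correlation; 1 of 13 rose, 2 adjusted over the list alone) and cholesterol biosynthesis (0.00386, but adjusted p = 0.379 with an estimated correlation). This count was 3 without epiblast E6.5 replicate 1, 0 without epiblast E6.5 replicate 2 (limma, 2637 at an unadjusted p under 0.05), 22 without epiblast E5.75 replicate 1 (10 higher and 12 lower) and 155 without epiblast E5.75 replicate 2. Mixl1 passed in 3 of these 4 fits and not without epiblast E6.5 replicate 2. Daam1 and H4c9 passed in 2, and not without either epiblast E6.5 array, and Dppa2 only without epiblast E5.75 replicate 2. Of the 3 genes without epiblast E6.5 replicate 1 only 1 is among the 5 reported. No gene passed in a fit on the 4 arrays compared (limma, 1333 at an unadjusted p under 0.05) or with array weights (limma, 1319 at an unadjusted p under 0.05). With each array centred on its own median only the 3 genes that rose passed. Of Mixl1, Daam1, Dppa2 and H4c9 only Mixl1 passed over every probe set.

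Lines of rsEpiSC E5.75 were compared with epiblast E5.75 to ask how cells in this culture differ from the tissue of the same stage. The median of all genes was -0.16 in this comparison and 0.02 once each array was centred on its own median, so list medians here are given relative to the median of all genes. All 17 measured cholesterol biosynthesis genes rose in rsEpiSC (17 adjusted over the list alone), by a relative median of 1.96, among them Dhcr7 (3.63 ± 0.28, adjusted p = 2.17e-05), Mvd (3.09 ± 0.33), Fdps (2.83 ± 0.28) and Insig1 (2.54 ± 0.53). Germline genes fell in 11 of 15 cases (12 adjusted over the list alone; relative median -1.14), such as the meiosis genes Hormad1 (-3.66 ± 0.73) and Sycp1 (-2.95 ± 0.36) and the piRNA pathway gene Mael (-2.95 ± 0.40). Of 14 anterior and neural genes 6 rose (6 adjusted over the list alone; relative median 1.12), including Sox1 (3.73 ± 0.31), Rax (2.75 ± 0.33), Lhx5 (2.68 ± 0.40) and Hesx1 (2.51 ± 0.61). Fgf5 (-4.75 ± 0.65, adjusted p = 0.000655) and Dnmt3b (-3.28 ± 0.55, adjusted p = 0.00209) fell. So did Nanog (-1.97 ± 0.35) and Pou5f1 (-1.36 ± 0.33). No difference passed for Otx2 (-0.02 ± 0.33, adjusted p = 0.964), Sox2 (0.43 ± 0.24, adjusted p = 0.213), Zfp42 (-0.97 ± 0.42, adjusted p = 0.117) and Xist (0.29 ± 0.54, adjusted p = 0.72).

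Of 27 oxidative phosphorylation genes 11 rose (12 adjusted over the list alone; relative median 0.55, but 0.26 after quantile normalization), such as Sdhc (2.58 ± 0.29), Cox4i1 (2.42 ± 0.31) and Atp5b (1.45 ± 0.27). Of 17 glycolysis genes 7 rose (9 adjusted over the list alone; relative median 0.86, but 0.57 after quantile normalization), such as the glucose transporter gene Slc2a3 (2.92 ± 0.34) and Aldoc (2.29 ± 0.34). Neither list passed with an estimated correlation (adjusted p = 0.367 for both). Of 13 p53 targets 6 rose and 1 fell (7 and 1 adjusted over the list alone), among them the cell cycle inhibitor gene Cdkn1a (3.53 ± 0.47), Sesn2 (2.19 ± 0.54) and Pmaip1 (-2.63 ± 0.55). Of 18 immediate early and stress genes 4 rose and 1 fell (4 and 1 adjusted over the list alone), including Ddit4 (3.62 ± 0.37), Egr1 (3.05 ± 0.46), Jun (2.77 ± 0.43) and Hspa1b (-3.25 ± 0.46). Of 15 FGF/ERK targets 4 rose and 1 fell (4 and 1 adjusted over the list alone), such as Phlda1 (2.41 ± 0.41) and Dusp4 (2.15 ± 0.36). Of 18 cell cycle genes 5 rose (5 adjusted over the list alone), such as Cdc20 (2.10 ± 0.40) and Aurkb (1.58 ± 0.21). Fibroblast markers rose in 4 of 17 cases and fell in 1 (4 and 3 adjusted over the list alone; camera adjusted p = 0.366), with Col1a2 at 3.37 ± 0.63 and Dcn at -2.14 ± 0.30. Among the lowest of all genes were Rpl10l (-6.38 ± 0.44), Platr10 (-6.07 ± 0.39), Cyct (-6.06 ± 0.35) and Fthl17e (-5.70 ± 0.67). Among the highest were H2ac15 (5.48 ± 0.76), Ccnd2 (5.37 ± 0.53), Mid1 (5.07 ± 0.26) and Greb1l (4.54 ± 0.34).

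Between rsEpiSC E5.75 and epiblast E5.75 4768 of 22180 genes passed in limma, 3562 by at least 2-fold. Of these 2550 rose and 2218 fell (53.5% higher), against 3076 and 1243 (71.2% higher) with each array centred on its own median. Without epiblast E5.75 replicate 2 more genes fell (2780) than rose (2724). After quantile normalization the relative medians shrank to 0.53 for FGF/ERK targets (0.96 as reported), 0.05 for the cell cycle (0.39), 0.67 for stress genes (1.04) and 0.62 for p53 targets (1.01). Camera passed 9 lists at the preset correlation: cholesterol biosynthesis (1.17e-14, but adjusted p = 0.0554 with an estimated correlation), anterior and neural ectoderm (0.000218, but adjusted p = 0.0554 with an estimated correlation) and germline genes (1.01e-07, but adjusted p = 0.0587 with an estimated correlation). Others were oxidative phosphorylation (6.58e-06), glycolysis (0.000283) and stress genes (0.0112), each with adjusted p = 0.367 with an estimated correlation, and p53 targets (0.00444), the cell cycle (0.00597) and FGF/ERK targets (0.0116), each with adjusted p = 0.389 with an estimated correlation. The count of genes was 1627 without rsEpiSC E5.75 replicate 1, 1755 without rsEpiSC E5.75 replicate 2, 3031 without epiblast E5.75 replicate 1 and 2909 in a fit on the 4 arrays compared. Of 41 named genes that passed, 40 still did without rsEpiSC E5.75 replicate 1, 37 without rsEpiSC E5.75 replicate 2, 38 without epiblast E5.75 replicate 1 and 40 without epiblast E5.75 replicate 2. Those lost were Pou5f1, Hesx1, Insig1, Sesn2 and Pmaip1.

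**Figure D4:**
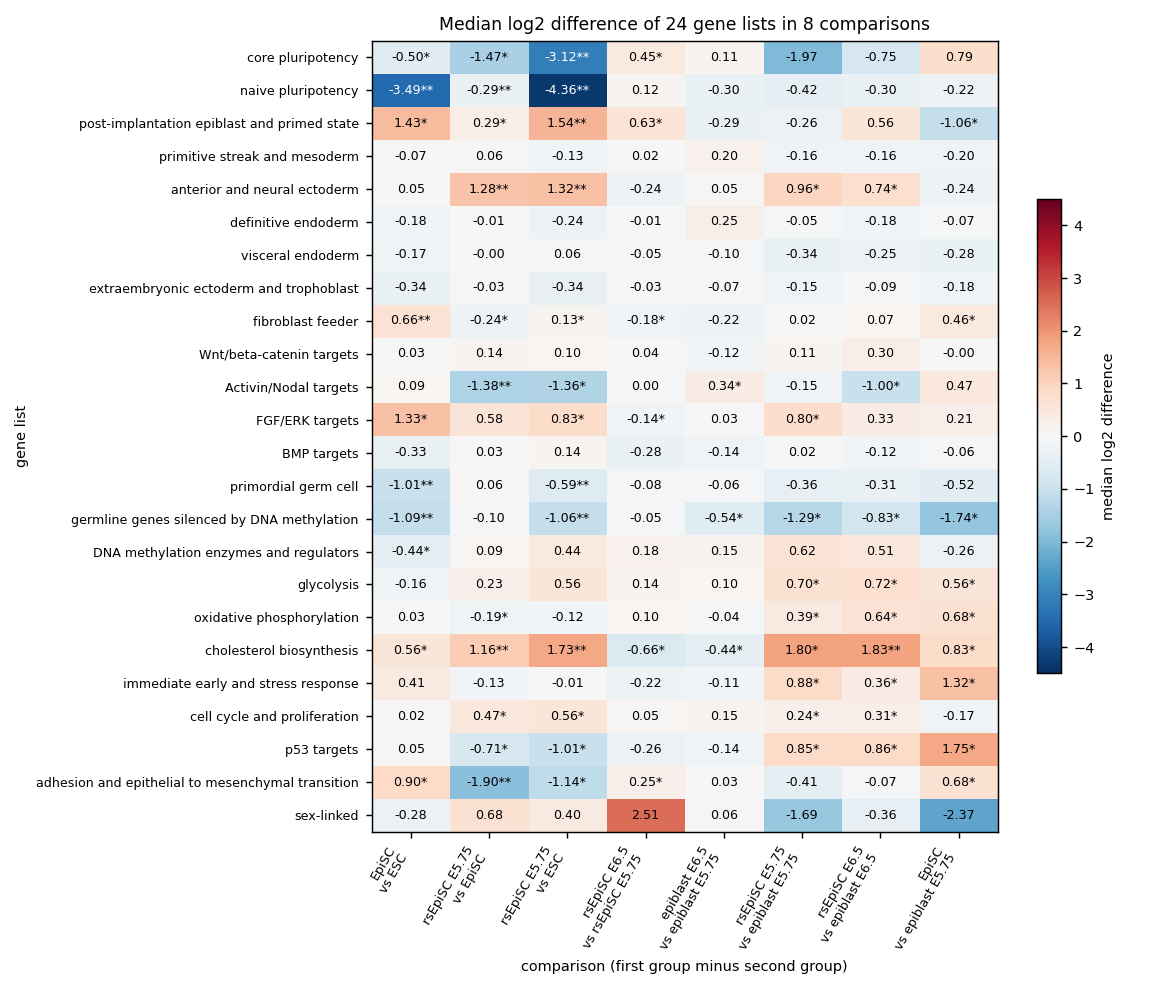
Median log2 difference of the measured members of 24 gene lists (y axis) in 8 comparisons (x axis), where 1 star marks a camera adjusted p under 0.05 at the preset correlation and a pair of stars marks one that also held with an estimated correlation. Medians run from -4.36 for naive pluripotency in rsEpiSC E5.75 against ESC to 2.51 for the 4 sex-linked genes between the rsEpiSC groups.

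Lines of rsEpiSC E6.5 were compared with epiblast E6.5 to ask the same of the later stage. The median of all genes was -0.10 and -0.02 with centred arrays, and list medians are relative to the median of all genes. Cholesterol biosynthesis genes rose in 15 of 17 cases (17 adjusted over the list alone; relative median 1.93), such as Fdps (3.11 ± 0.28), Msmo1 (2.82 ± 0.35) and Insig1 (2.65 ± 0.53). Oxidative phosphorylation genes rose in 14 of 27 cases (17 adjusted over the list alone; relative median 0.74), such as Cox4i1 (2.48 ± 0.31) and Uqcrc1 (1.94 ± 0.20). Anterior and neural genes rose in 4 of 14 cases (adjusted over the list alone, 5 rose and 1 fell; relative median 0.84), among them Sox1 (3.70 ± 0.31), Hesx1 (3.51 ± 0.61) and Lhx5 (2.44 ± 0.40). Activin/Nodal targets fell in 5 of 13 cases and rose in 1 (7 and 2 adjusted over the list alone), including Tdgf1 (-5.30 ± 0.61), Eomes (-3.77 ± 0.26), Mixl1 (-3.44 ± 0.37) and Skil (-3.33 ± 0.30). Germline genes fell in 5 of 15 cases (9 adjusted over the list alone; relative median -0.73), such as Ddx4 (-3.13 ± 0.26) and Mael (-2.82 ± 0.40). Glycolysis genes rose in 4 of 17 cases (7 adjusted over the list alone), such as Slc2a3 (2.33 ± 0.34). Targets of p53 rose in 4 of 13 cases and fell in 1 (6 and 1 adjusted over the list alone), such as Sesn2 (3.06 ± 0.54). Cell cycle genes rose in 3 of 18 cases (adjusted over the list alone, 6 rose and 1 fell), such as Cdc20 (1.72 ± 0.40). Stress genes rose in 3 of 18 cases (3 adjusted over the list alone), such as Ddit4 (3.81 ± 0.37). Fgf5 (-2.65 ± 0.65, adjusted p = 0.0222) and Nanog (-2.29 ± 0.35) fell. Dnmt3b (-1.57 ± 0.55, adjusted p = 0.0806) and Pou5f1 (-0.75 ± 0.33, adjusted p = 0.155) did not pass. Xist fell as well (-5.76 ± 0.54). The tissue arrays of both stages had high signals both of Xist (8.41 to 9.05) and of Eif2s3y (8.10 to 8.55), so the tissue may hold embryos of both sexes. The Xist difference cannot be told apart from the sex of the samples.

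Between rsEpiSC E6.5 and epiblast E6.5 2772 of 22180 genes passed in limma, 2191 by at least 2-fold. Of these 1491 rose and 1281 fell (53.8% higher), against 1587 and 910 (63.6% higher) with each array centred on its own median. Camera passed cholesterol biosynthesis (4.18e-17) and 8 further lists at the preset correlation, of which anterior and neural ectoderm had 0.000273, but adjusted p = 0.0658 with an estimated correlation, and germline genes 2.97e-05, but adjusted p = 0.15 with an estimated correlation. For Activin/Nodal targets (0.000273) and oxidative phosphorylation (3.16e-10) it was adjusted p = 0.156 with an estimated correlation, and for glycolysis (9.6e-05) adjusted p = 0.302 with an estimated correlation. Stress genes (0.0211, but adjusted p = 0.305 with an estimated correlation), p53 targets (0.00297, but adjusted p = 0.41 with an estimated correlation) and the cell cycle (0.0211, but adjusted p = 0.487 with an estimated correlation) were the remaining 3. After quantile normalization the relative median of the cell cycle list was 0.13 (0.41 as reported), that of stress genes 0.22 (0.46), that of glycolysis 0.49 (0.82) and that of oxidative phosphorylation 0.42 (0.74). Left-out arrays moved the count of genes to 751 without rsEpiSC E6.5 replicate 1, 553 without rsEpiSC E6.5 replicate 2 and 1481 without epiblast E6.5 replicate 1. Of 21 named genes that passed, 18 still did without rsEpiSC E6.5 replicate 1 or without epiblast E6.5 replicate 1 and 19 without either of the other arrays. Those lost were Fgf5, Cdc20, Insig1 and Sesn2.

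The comparison of EpiSC with epiblast E5.75 asks how the older culture condition differs from tissue of that stage. The median of all genes was -0.19 and 0.04 with centred arrays, and list medians are again relative to the median of all genes. Targets of p53 rose in 11 of 13 cases and fell in 1 (12 and 1 adjusted over the list alone; relative median 1.93), among them Cdkn1a (4.85 ± 0.47), Perp (3.13 ± 0.70), Trp53inp1 (3.05 ± 0.54) and Sesn2 (2.89 ± 0.54). Primed state genes fell in 8 of 14 cases (8 adjusted over the list alone; relative median -0.87), including Fgf5 (-3.44 ± 0.65, adjusted p = 0.00342), Dnmt3b (-3.06 ± 0.55), Cdh2 (-2.81 ± 0.60), Lef1 (-2.62 ± 0.27) and Otx2 (-1.72 ± 0.33). Germline genes fell in 11 of 15 cases (12 adjusted over the list alone; relative median -1.55), such as Hormad1 (-3.55 ± 0.73) and Sycp1 (-3.04 ± 0.36). Of 27 oxidative phosphorylation genes 15 rose (18 adjusted over the list alone; relative median 0.86), such as Cox4i1 (2.66 ± 0.31). Cholesterol biosynthesis genes rose in 8 of 17 cases (9 adjusted over the list alone; relative median 1.02), such as Dhcr7 (2.23 ± 0.28). Glycolysis genes rose in 4 of 17 cases and fell in 1 (4 and 1 adjusted over the list alone), with Slc2a3 at 3.19 ± 0.34 and Pdk1 at -3.81 ± 0.75. Sox2 fell (-2.83 ± 0.24), Nanog rose (1.49 ± 0.35, adjusted p = 0.0103), and Pou5f1 did not pass (0.11 ± 0.33, adjusted p = 0.823).

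Stress genes rose in 10 of 18 cases and fell in 1 (10 and 2 adjusted over the list alone), such as Ddit4 (3.61 ± 0.37), Ddit3 (3.34 ± 0.58) and Hspa1b (-2.98 ± 0.46). The adhesion list had 7 of 19 members that rose and 2 that fell (7 and 2 adjusted over the list alone), including Krt18 (3.08 ± 0.28), Vim (2.90 ± 0.50) and Cdh3 (2.84 ± 0.35). Fibroblast markers rose in 7 of 17 cases and fell in 1 (7 and 1 adjusted over the list alone), such as Tagln (3.87 ± 0.34), Acta2 (3.43 ± 0.33) and Col1a2 (3.24 ± 0.63). Among the highest were the basement membrane gene Nid1 (6.30 ± 0.48), Cryab (5.75 ± 0.47) and Anxa3 (5.44 ± 0.55). Among the lowest were Cyct (-6.42 ± 0.35), Fthl17e (-5.92 ± 0.67) and Eif2s3y (-5.87 ± 1.30), which had 8.31 and 8.10 on the tissue arrays. The Eif2s3y difference cannot be told apart from the sex of the samples. In limma 5321 of 22180 genes passed, 3900 by at least 2-fold, of which 2793 rose and 2528 fell (52.5% higher), against 3545 and 1157 (75.4% higher) with each array centred on its own median. Without epiblast E5.75 replicate 2 more genes fell (3132) than rose (2968). After quantile normalization the relative medians were 0.35 for glycolysis (0.75 as reported), 0.55 for oxidative phosphorylation, 0.64 for cholesterol biosynthesis and -1.32 for the primed state. Camera passed primed state genes (0.00154, but adjusted p = 0.22 with an estimated correlation) and glycolysis (0.0101, but adjusted p = 0.471 with an estimated correlation). For p53 targets (2.41e-07), germline genes (4.7e-07), oxidative phosphorylation (4.75e-08), cholesterol biosynthesis (3.09e-05), stress genes (0.000691), adhesion (0.00154) and fibroblast markers (0.0312) it was adjusted p = 0.162 with an estimated correlation. The count of genes was 2458 without EpiSC replicate 1, 3224 without EpiSC replicate 2, 3501 without epiblast E5.75 replicate 1, 2316 in a fit on the 4 arrays compared and 3261 with array weights. Of 32 named genes that passed, 28 still did without EpiSC replicate 1 and 30 without epiblast E5.75 replicate 1, with Nanog, Perp, Cdh2 and Eif2s3y the ones that did not.

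Each cultured array was also correlated across genes with the mean of each tissue group, to ask which cultured cells lie nearest to the epiblast. The Pearson correlation with epiblast E5.75 was 0.905 ± 0.008 for ESC, 0.907 ± 0.012 for EpiSC, 0.918 ± 0.001 for rsEpiSC E5.75 and 0.934 ± 0.004 for rsEpiSC E6.5 (mean ± SD of 2 arrays). With epiblast E6.5 it was 0.906 ± 0.008, 0.913 ± 0.013, 0.926 ± 0.001 and 0.941 ± 0.003. Over the 1000 genes that varied most it was 0.339, 0.390, 0.400 and 0.513 with epiblast E5.75, and 0.307, 0.451, 0.477 and 0.591 with epiblast E6.5. The root mean square log2 difference from epiblast E6.5 was 0.926 for ESC, 0.904 for EpiSC, 0.828 for rsEpiSC E5.75 and 0.746 for rsEpiSC E6.5. Spread between arrays lowers such correlations, and it differed between the groups. Replicates correlated at 0.965 in ESC and 0.976 in EpiSC, against 0.986 in rsEpiSC E5.75 and 0.988 in rsEpiSC E6.5. Part of the order of the groups may therefore come from this spread. These values were not tested.

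**Figure D5:**
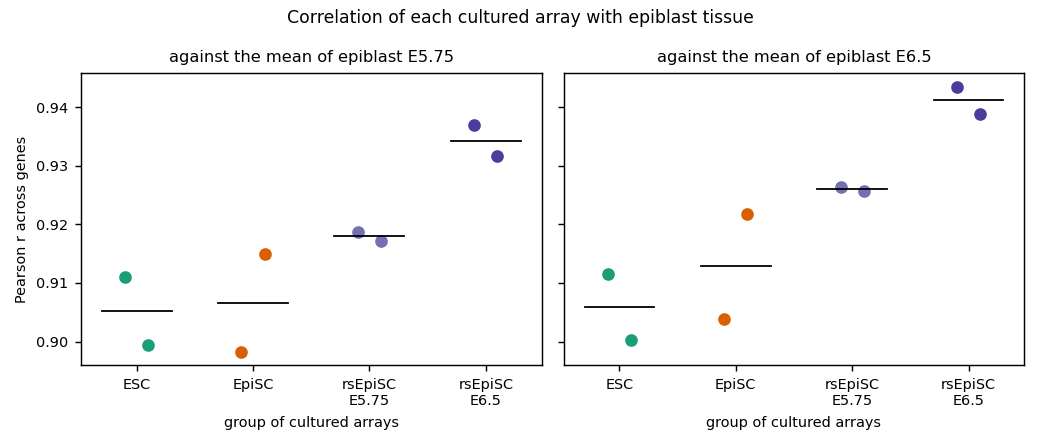
Pearson correlation across 22180 genes (y axis) of each cultured array with the mean of a tissue group, by culture group (x axis), where each point is 1 array and each line the mean of 2 arrays. Means ran from 0.905 for ESC with epiblast E5.75 to 0.941 for rsEpiSC E6.5 with epiblast E6.5.

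The last comparison asks whether the difference between stages in rsEpiSC differs from that in the tissue, with an interaction term. Xist (-6.05 ± 0.76, adjusted p = 0.0451) and Mid1 (-4.27 ± 0.37, adjusted p = 0.00159), both on the X chromosome, passed. The Xist value cannot be told apart from the sex of the samples. Mixl1 (-3.62 ± 0.52, adjusted p = 0.0636), Utf1 (3.21 ± 0.52, adjusted p = 0.0875), Fgf5 (2.10 ± 0.92, adjusted p = 0.561) and Dnmt3b (1.70 ± 0.78, adjusted p = 0.577) did not pass. All 14 primed state genes had positive values (median 0.88), none passing in limma (7 at an unadjusted p under 0.05). Camera passed this list (0.000108, but adjusted p = 0.595 with an estimated correlation) and germline genes (0.0239, but adjusted p = 0.606 with an estimated correlation; median 0.24, none passing in limma and 4 at an unadjusted p under 0.05). Limma passed these 2 genes of 22180, and 1919 had an unadjusted p under 0.05. The count was 1 without rsEpiSC E6.5 replicate 1, rsEpiSC E5.75 replicate 2, epiblast E6.5 replicate 2 or epiblast E5.75 replicate 2, and 5 without epiblast E5.75 replicate 1. Mid1 passed whichever array was left out and Xist only without rsEpiSC E5.75 replicate 1. Neither passed with the mean of a gene's probe sets, and only Mid1 over every probe set or after quantile normalization. With the X and Y genes left out no gene passed in limma (1837 at an unadjusted p under 0.05). Across 22180 genes the stage differences of the cultured lines and of the tissue had a Pearson correlation of -0.01 and a Spearman correlation of -0.02, and 46.8% of the 2819 genes at an unadjusted p under 0.05 in the tissue had the same sign in rsEpiSC. Of the 5 genes that passed in the tissue 1 had the same sign.

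With an estimated correlation camera kept 4 list calls in EpiSC against ESC (naive pluripotency, primordial germ cell, germline and fibroblast genes). It kept 5 in rsEpiSC E5.75 against EpiSC (naive pluripotency, anterior and neural ectoderm, Activin/Nodal targets, cholesterol biosynthesis and adhesion). In rsEpiSC E5.75 against ESC it kept 7 (core and naive pluripotency, the primed state, anterior and neural ectoderm, cholesterol biosynthesis, germline and primordial germ cell genes), and in rsEpiSC E6.5 against epiblast E6.5 only cholesterol biosynthesis. It kept no list in the other 5 comparisons, where camera with an estimated correlation gave 4 lists at an unadjusted p under 0.05 between the rsEpiSC groups, 2 between the tissue stages, 3 in rsEpiSC E5.75 and 7 in EpiSC against epiblast E5.75, and 2 for the interaction. The rotation test fry passed 14 lists in rsEpiSC E5.75 and 11 in EpiSC against epiblast E5.75, and none in the other 3 (4, 6 and 2 lists at an unadjusted p under 0.05). In no comparison did a list that passed at the preset correlation differ in sign between its median, its mean and its test, or change the sign of its median with quantile normalization or with centred arrays.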

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

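The tests of X and Y genes, of germ cells in the tissue and of a minority of differentiated cells were chosen after their results had been seen. The stage difference in rsEpiSC minus that in epiblast was -6.05 ± 0.76 for Xist (limma interaction, adjusted p = 0.0451) and -4.27 ± 0.37 for Mid1 (adjusted p = 0.00159). Mean Xist was 9.21 in rsEpiSC E5.75, 2.91 in rsEpiSC E6.5, 8.92 in epiblast E5.75 and 8.67 in epiblast E6.5, and mean Mid1 was 10.63, 6.81, 5.56 and 6.01. Among probe sets without a single gene name, which the reported comparisons leave out, 114 of 17824 passed in limma between rsEpiSC E5.75 and EpiSC, 53 higher and 61 lower.

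Genes of the X and Y chromosomes made up 4 of the 19 genes that passed between the rsEpiSC groups (21.1%, against 4.2% of all genes, 2-sided Fisher's exact p = 0.00702). Xist, which raised the question of sex, is among these 4, so this p-value is not independent support. Mid1 is also among them and did not follow Xist over the groups. Mean Mid1 was 5.56 in epiblast E5.75 and 6.81 in rsEpiSC E6.5, where mean Xist was 8.92 and 2.91. Xist was lower and Eif2s3y higher on both rsEpiSC E6.5 arrays than on either rsEpiSC E5.75 array. Lines of different sex in the 2 groups could give this. On rsEpiSC E5.75 replicate 1, however, Xist was 8.23 and Eif2s3y 5.16, against 10.19 and 2.33 on replicate 2. Replicate 1 thus had both signals, and the rsEpiSC E5.75 group may not be of 1 sex. For the 15 autosomal genes, rsEpiSC E5.75 replicate 1, which has the higher Y-linked signal of its group, lay nearer to the rsEpiSC E6.5 mean in 10. Chance bounds for independent genes are 4 and 11, but all 15 genes compare the same 2 arrays. The count therefore decides nothing, and sex and stage of derivation cannot be told apart for these genes. The stage of derivation itself was not tested apart from the lines.

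Germline genes were lower in rsEpiSC E5.75 than in epiblast E5.75 by a median of -1.30, or -1.14 relative to all genes (camera adjusted p = 1.01e-07, but adjusted p = 0.0587 with an estimated correlation). The raw median is used here. The narrower range of the tissue arrays as the whole cause is argued against by random lists of the same size and mean signal. Their median was -0.32, and the germline median lay at percentile 0.01 among them (the smallest the draw gives). These lists hold unrelated genes, so the percentile does not allow for germline genes that vary together. The germline list was also taken up because it was lower in this comparison, so the percentile is not independent of the camera test. Primordial germ cells begin to form near E6.25, which is later than the E5.75 tissue compared here. The germline median of epiblast E6.5 minus epiblast E5.75 was -0.54 (standard error 0.31 over genes, 12 of 15 lower). This list showed no rise at the stage when such cells appear, but it shares no gene with the list of primordial germ cell genes. It need not rise where such cells are present, and its spread is wide. This test therefore decides nothing about such cells. A difference between culture and embryo stays open and was not tested.

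Activin/Nodal targets and genes of the adhesion list were lower in rsEpiSC E5.75 than in EpiSC. A minority of differentiated cells, at equal RNA per cell, lowers a gene by less than 1 on the log2 scale. As the whole cause it is argued against for 10 of 32 measured members, lower by more than 1 in limma treat (adjusted p under 0.05). Over all genes 73 were lower by more than 1 in this test. Both lists were chosen because they fell in this comparison, so their count was not set against chance. Of these 10 members 8 belong to the adhesion list and 2 to the Activin/Nodal list. The median of all 32 was -1.48 (standard error 0.601 over genes). Differentiated cells in a minority may still add to the changes of members that did not pass this test. More feeder cells are argued against by the fibroblast list, with a median of -0.24 (standard error 0.19 over genes, 17 members). These tests bear only on a minority of differentiated cells and on feeder cells. Differentiation of most of the rsEpiSC E5.75 cells stays open and was not tested. The media, of which only that of EpiSC is given with Activin A, and other differences between the lines also stay open and were not tested.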

How the results depend on the processing

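Checks chosen after seeing the data are the fit on the 8 cultured arrays, the fits without X and Y genes and the crossed pairing of replicates. The replicate numbers do not pair the arrays: deviations of same-numbered arrays correlated between -0.042 and 0.058, apart from -0.26 between ESC and EpiSC. The replicate block gave 1 gene instead of 5 between the tissue stages and 1 instead of 2 for the interaction, where Xist no longer passed. Of the other named genes it ended the calls of Lin28a and Mmp2 in EpiSC against ESC, of Ddit3, Eomes, Mcm3, Mvd, Perp and S100a4 in rsEpiSC E5.75 against EpiSC, and of Daam1, Dppa2 and H4c9 between the tissue stages, and it left 5 of 6 lists between the rsEpiSC groups. It changed no other call of a named gene and no other number of lists. The mean of probe sets ended the call of Cdh2 in EpiSC against epiblast, and every probe set that of Fgf5 in rsEpiSC E6.5 against epiblast. The crossed pairing gave 1461 genes in EpiSC against ESC, against 1396 reported and 1288 with the block.

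Leaving out 1 array at a time gave 829 to 1388 genes in EpiSC against ESC, 318 to 626 in rsEpiSC E5.75 against EpiSC, 1027 to 2065 in rsEpiSC E5.75 against ESC, 3 to 15 between the rsEpiSC groups, 0 to 155 between the tissue stages, 1627 to 5504 in rsEpiSC E5.75 against epiblast, 553 to 1872 in rsEpiSC E6.5 against epiblast, 2458 to 6100 in EpiSC against epiblast and 1 to 5 for the interaction. Fits on only the arrays compared gave 558 genes in EpiSC against ESC, 157 between the rsEpiSC groups, 2909 in rsEpiSC E5.75 and 2316 in EpiSC against epiblast, 7 for the interaction and 0 between the tissue stages (limma, 1333 at an unadjusted p under 0.05). Array weights gave 1567 genes in rsEpiSC E5.75 against EpiSC, 257 between the rsEpiSC groups, 3261 in EpiSC against epiblast, 1 for the interaction and 0 between the tissue stages (limma, 1319 at an unadjusted p under 0.05). Between the tissue stages the count was 8 without dim genes, 10 over every probe set, 13 after quantile normalization and 3 with centred arrays. For the interaction it was 7 without dim genes, 0 with the mean of probe sets (limma, 1912 at an unadjusted p under 0.05), 1 over every probe set, 1 after quantile normalization, 5 with centred arrays (1 higher and 4 lower), 4 with eBayes without trend and 0 without X and Y genes (limma, 1837 at an unadjusted p under 0.05). Between the rsEpiSC groups the 8 cultured arrays gave 10 genes. All other alternatives stayed within 1.5 times the reported counts. With dim genes left out 2628 rose and 1209 fell in rsEpiSC E5.75, 1586 and 807 in rsEpiSC E6.5 and 2878 and 1462 in EpiSC against epiblast of the same stage. The cause of these shifts was not tested.

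With an estimated correlation camera passed 4, 5, 7, 0, 0, 0, 1, 0 and 0 lists, in the order of the comparisons above, against 10, 11, 13, 6, 3, 9, 9, 9 and 2 at the preset correlation. The rotation test fry passed 14 lists in rsEpiSC E5.75 against epiblast and 0 between the rsEpiSC groups, between the tissue stages and for the interaction (4, 6 and 2 at an unadjusted p under 0.05).

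The correlations with epiblast E5.75 for ESC, EpiSC, rsEpiSC E5.75 and rsEpiSC E6.5 were 0.339, 0.390, 0.400 and 0.513 over the 1000 most variable genes and 0.837, 0.837, 0.859 and 0.890 without dim genes, and 0.880 to 0.904, 0.880 to 0.906, 0.892 to 0.917 and 0.909 to 0.932 leaving out 1 tissue array. With epiblast E6.5 they were 0.307, 0.451, 0.477 and 0.591, then 0.836, 0.847, 0.873 and 0.902, and 0.897 to 0.898, 0.904 to 0.905, 0.917 to 0.918 and 0.931 to 0.934. The value for rsEpiSC E6.5 was the highest of the 4 groups in each of these. The correlation of stage differences between culture and tissue ran from -0.031 to 0.010 leaving out 1 array, positive without epiblast E6.5 replicate 1.

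No named gene that passed reversed its sign in an alternative. Of those that did not pass, leaving out 1 array gave ranges from -1.05 to 0.91 for Xist, -0.15 to 0.47 for Esrrb, -1.08 to 0.65 for Dnmt3b and -2.64 to 0.032 for Fgf5 in rsEpiSC E5.75 against EpiSC. Against epiblast E5.75 they were -0.69 to 1.27 for Xist and -0.062 to 0.012 for Otx2 in rsEpiSC E5.75 and -0.070 to 0.29 for Pou5f1 in EpiSC. Otx2 was at 0.15 there with centred arrays, and Pou5f1 at -0.19 after quantile normalization.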

Other observations

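The genes of both patterns below were chosen after their values were seen, and the tests use other genes of the same regions. The random lists hold unrelated genes, so their percentiles do not allow for neighbouring genes that vary together. In EpiSC the maternally expressed long RNAs of the imprinted Dlk1-Dio3 region fell against ESC, Meg3 by -1.63 ± 0.36 (adjusted p = 0.0166) and Rian by -4.06 ± 0.38 (adjusted p = 5.95e-05), as did the small nucleolar RNAs AF357425 (-5.74 ± 0.47) and AF357426 (-5.05 ± 0.55). All 4 rose in rsEpiSC E5.75 against EpiSC, Meg3 by 1.49 (adjusted p = 0.0391) and Rian by 3.85 (adjusted p = 0.000217). The 43 microRNA loci of the region, at a median signal of 3.29, had a median of -0.28 in EpiSC against the mean of the other groups, with 40 of 43 lower, at percentile 0.52 of random lists matched on mean signal, whose median was -0.17. These loci lie near the low end of the signal range and their fall is small beside that of Meg3 and Rian. A fall shared by the maternally expressed transcripts of the region in these EpiSC is a candidate explanation that these loci support only weakly. Imprinting was not measured.

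The zinc finger genes Zfp979, Zfp980, Zfp981, Zfp982, Zfp985 and Zfp992 lie on chromosome 4 and were lower in rsEpiSC E5.75 than in epiblast E5.75, by -4.62, -4.00, -5.00, -3.60, -3.51 and -5.12. Their means were also lower in EpiSC and rsEpiSC E6.5 than in epiblast of the same stage, so this is not particular to rsEpiSC E5.75. In EpiSC against epiblast E5.75, Zfp982 was at 5.39 against 5.93 and Zfp992 at 3.91 against 8.67. Mean Zfp992 in ESC was 10.26. The 8 other measured genes between them had a median of -1.63, at percentile 0.01 of random lists matched on mean signal (the smallest the draw gives), with 6 that fell in limma. A fall shared by the cluster may therefore be at work, but these genes are related in sequence and probes could respond to several of them, which was not tested.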
